A study of Macaca mulatta with 4 samples.

How the data were processed

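RNA from the amygdala of rhesus macaques (Macaca mulatta) was sequenced in 4 libraries, 2 from controls and 2 from animals that had inhaled sevoflurane, a halogenated ether used as a general anaesthetic. Each condition held 1 female and 1 male. Per the labels' protocols, the animals breathed about 2.5 to 3% sevoflurane for 4 hours at about postnatal days 7, 21 and 35, and the tissue was taken right after the last of the 3 exposures. What the controls breathed is not given in the sources used here. Total RNA was extracted with a phenol-based reagent, its integrity was checked by capillary electrophoresis, and libraries followed the standard Illumina procedure, per the labels' protocols. Whether that procedure selected poly(A) RNA, whether it kept strand, and whether the 4 libraries were prepared together are not given in the sources used here.

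The deposited table holds raw read counts per gene, not normalized, with 1 column per library and 35395 Ensembl macaque gene IDs. Per the submitters' processing notes, reads were aligned with HISAT2; its version, the counting program, the genome build and the annotation release are not given in the sources used here. No genome of the authors' build was used, so no gene positions, lengths or base compositions are given. Symbols were taken from a table of gene IDs, which named 24173 of the IDs in the file. Every sample column was used. Reads on genes ranged from 12477047 in the control male library to 16293371 in the control female library, with 14413858 in the sevoflurane female and 13615927 in the sevoflurane male library. Genes that share reads with a near-identical copy or an overlapping gene are uncertain, since the counting rule is unknown.

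Groups came from the treatment label and sex from the sex label. The labels give no replicate numbers, so replicate 1 (female) and replicate 2 (male) are only names. They do not state that libraries of a group are separate animals beyond their difference in sex. The p-values therefore measure the spread between these libraries, and within a condition that spread includes the difference between the sexes.

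Low-count genes were removed with edgeR's filterByExpr (minimum count 10, by group), which left 15417 genes, 13819 of them with a symbol. Counts were scaled with TMM, and the factors were 0.942 for the control female, 0.904 for the control male, 1.10 for the sevoflurane female and 1.07 for the sevoflurane male library. Sevoflurane was compared with control by edgeR's quasi-likelihood F-test with condition as the only term and 2 residual degrees of freedom. Males were compared with females in the same way with condition and sex as terms and 1 residual degree of freedom. The remaining way of parting the 4 libraries 2 against 2 was tested with the split as the only term. That leaves the difference between conditions in its residual. A gene was called at a Benjamini-Hochberg adjusted p under 0.05. Standard errors of log2 fold changes were derived from the F statistic. Levels are CPM with TMM scaling, given as mean ± SD over 2 libraries. Changes are relative to the TMM scaling. With library totals alone the median log2 fold change of all tested genes was 0.24, against 0.0040 with TMM.

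Before the data were examined, 33 gene lists of pathways and cell types were fixed from general knowledge: immediate early genes, GABA-A and glycine receptor subunits, ionotropic glutamate receptor subunits, background potassium and HCN channels, synaptic vesicle and scaffold genes, heat shock genes, unfolded protein response genes, hypoxia and glycolysis genes, glucocorticoid-responsive genes, circadian clock genes, inflammatory genes, apoptosis genes, cholesterol synthesis genes, regulators of the RNA mark m6A, nuclear respiratory chain genes, neuropeptide genes, and markers of oligodendrocytes, their precursors, astrocytes, microglia, endothelium, pericytes and smooth muscle, fibroblasts, choroid plexus, ependyma, red blood cells, excitatory, inhibitory, striatal-type, hippocampal, thalamic and hypothalamic and immature neurons, and proliferation. Of 604 listed symbols, 36 had no ID in the file, XIST among them. The 32 lists with at least 5 tested members were tested with limma's camera on log2 CPM (prior count 2) with a preset inter-gene correlation of 0.01. The alternatives were an estimated correlation and fry. The lists were also tested between the sexes, a choice made after seeing the data. After the genes of largest change had been seen, but before the values of their members were, lists of long messenger RNAs rich in A and U, long messenger RNAs rich in G and C, and short messenger RNAs (proteasome core and Sm spliceosome subunits) were written from general knowledge. Length and base composition were not measured, here or for any gene called short or long below. A list of 20 small and histone RNAs without a poly(A) tail was written with them.

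The named genes followed a rule fixed before the data were examined. It took the 10 rising and the 10 falling called genes of largest log2 fold change, with a symbol, an average of at least 1 log2 CPM and the same sign in both sexes. To these it added up to 4 called members of each list by smallest p (otherwise the 2 members of smallest p) and, for sex, the Y-linked genes and the 5 other genes of smallest p. Genes named outside the rule are marked as such, and some genes that the rule takes are not reported here. For a gene with no read in a group, the fold is a bound against a floor of 3 counts in each library. Intervals and floors cover counting error only, because reads copied by PCR are not independent molecules.

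The alternatives covered other scalings (RLE, upper quartile, library totals), no filter and a filter of at least 5 CPM in 2 libraries, DESeq2, limma-voom, thinning to the smallest library, removal of haemoglobin genes, sex as a covariate, and leaving out each library. No alternative removed mitochondrially encoded genes, because none was matched by symbol. A test against a 2-fold change (edgeR's glmTreat) was added after seeing the data. The versions were R 4.3.3, edgeR 4.0.16, limma 3.58.1 and DESeq2 1.42.0.

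The scripts were tested on simulated counts for the 15417 genes, with 200 genes changed. The sevoflurane comparison recovered 4% of 2-fold, 34% of 4-fold, 94% of 16-fold and 98% of 64-fold changes, with 6 false calls. The comparison of the sexes recovered 4%, 42%, 94% and 98% of the same sizes, with 2 false calls. In the list test, a simulated shift of the respiratory chain genes was called at an adjusted p of 5.07e-17 by limma's camera, and 0 other lists were called. The simulated genes were not correlated, so this result does not bear on the choice of inter-gene correlation.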

Results

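The amygdala, a group of nuclei in the temporal lobe, was profiled by RNA sequencing in infant macaques after repeated sevoflurane anaesthesia and in controls. The 4 libraries were 1 female (replicate 1) and 1 male (replicate 2) per condition, with 12477047 to 16293371 reads on genes each. At least 1 read was found for 18565 genes in the control female, 18371 in the control male, 19450 in the sevoflurane female and 19049 in the sevoflurane male library. The most abundant gene took 1.59% of reads in the control male library, where it was TTR, the transthyretin gene of the choroid plexus. In the other libraries it took 0.533% (TUBA1A, control female), 0.427% (HSP90AA1, sevoflurane female) and 0.403% (YWHAZ, sevoflurane male). Across tested genes, log2 CPM correlated at r = 0.944 between the 2 control libraries and 0.942 between the 2 sevoflurane libraries, and at 0.715 to 0.807 between conditions.

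The sex labels were checked with Y-linked genes. The 11 matched Y-linked genes together held 14 reads in the control female, 7632 in the control male, 263 in the sevoflurane female and 9663 in the sevoflurane male library. Of the 263 reads, 256 were on NLGN4Y, which has a near-identical X-linked copy and is therefore uncertain. Without NLGN4Y the sums were 11, 7276, 7 and 8572 reads, so each library matched its label.

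The main comparison asked which transcripts of the amygdala differed after the last of 3 sevoflurane exposures. In the sevoflurane libraries 12 of 17 GABA-A and glycine receptor subunits were called higher, as were 13 of 29 synaptic and 8 of 18 clock genes. Called lower were 25 of 35 respiratory chain subunits, 10 of 16 microglial markers and 9 of 29 immediate early genes. The synaptic and clock lists were not called as lists (limma's camera, adjusted p = 0.0578 and 0.0714). Classes of transcript moved as widely, with 31 of 35 long messenger RNAs rich in A and U called higher and 21 of 28 short ones lower. The design does not separate sevoflurane from a difference in handling. In all, 6278 genes were called by edgeR, 40.7% of the 15417 tested, with 3282 higher and 2996 lower. Among the called genes, 6277 moved the same way in both sexes, as did 85.3% of all tested genes. Opposite changes in the sexes widen the spread within a condition and hinder a call, so the value for called genes is no separate check. The median absolute log2 fold change of called genes was 2.01. At an absolute log2 fold change of at least 3, 1289 genes were higher and 283 lower. A change of more than 2-fold, tested with edgeR's glmTreat after seeing the data, was called for 3030 genes, 1891 higher and 1139 lower. With library totals in place of TMM, 63.3% of the called genes were higher, against 52.3% with TMM. Leaving out the sevoflurane male library lowered the count from 6278 to 3469 genes.

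The fold changes in females and in males share no library, and correlated at r = 0.859 (Spearman's rho = 0.851) across genes. Fold changes paired across the sexes gave r = 0.713 (rho = 0.724), and the male over female differences in the 2 conditions gave r = 0.325 (rho = 0.211). Genes are not independent replicates, so no p is attached to these values. With a filter of at least 5 CPM the first value was 0.913.

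**Figure D1:**
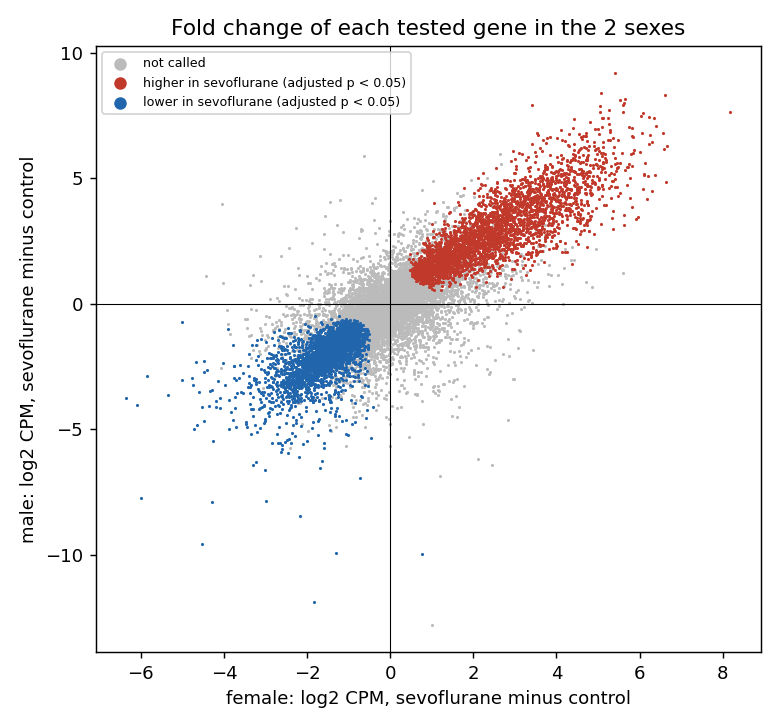
Log2 fold change (sevoflurane minus control, log2 CPM) of each tested gene in females (horizontal axis) and males (vertical axis), with 1 library per sex and condition. Red points are called higher, blue points called lower (edgeR, adjusted p under 0.05) and grey points not called; the values correlate at r = 0.859 across genes.

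The difference followed classes of transcript. Of 35 long messenger RNAs rich in A and U, 31 rose and 0 fell (32 called when adjusted over the list alone), with a median log2 fold change of 2.94. Of 29 long messenger RNAs rich in G and C, 8 rose and 2 fell (10 adjusted over the list alone), with a median of 0.52. Of this G- and C-rich list 0 fell without either male library and 1 without either female library. Of 28 short messenger RNAs, 0 rose and 21 fell (22 adjusted over the list alone), with a median of −1.46. Among 77 cytosolic ribosomal protein genes, a class of short messenger RNAs, 0 rose and 67 fell, with a median of −1.79. The median of the long A- and U-rich list minus that of the short list was −4.44 log2 in the control female and −4.71 in the control male library, against 1.10 in the sevoflurane female and 0.84 in the sevoflurane male library. These medians (2.94, 0.52 and −1.46) are the reference values for the gene groups that follow. The list of RNAs without a poly(A) tail, with 32 tested genes, had 6 that rose, 3 that fell (6 adjusted over the list alone) and a median of −0.19. That median was 0.69 without the control female and 1.58 without the control male library, in fits that tested 53 and 54 of these genes, and 1 to 3 rose without any 1 library.

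**Figure D2:**
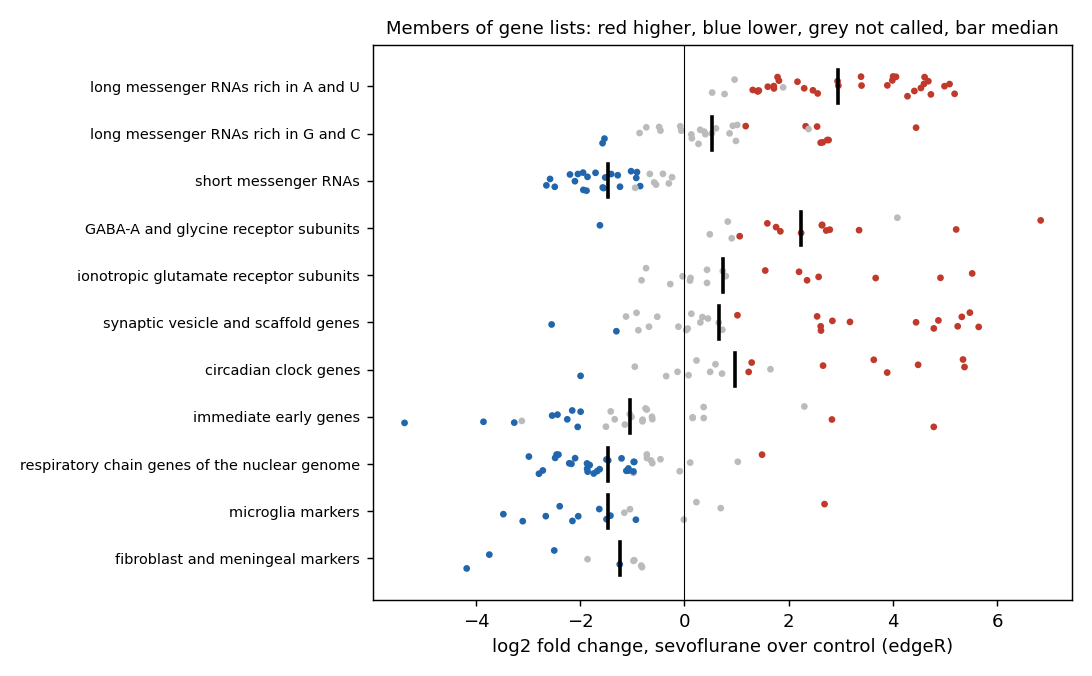
Log2 fold change (sevoflurane over control, edgeR) of each member of 11 gene lists, with red points called higher, blue points called lower, grey points not called and a black bar at the list median. The medians run from 2.94 for long messenger RNAs rich in A and U to −1.46 for short messenger RNAs and −1.46 for respiratory chain genes and microglia markers.

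The genes of largest rise were scarcely detected in controls. FAM217B, XK, NXT2, IGF2BP3, TRAPPC3L, ZNF280B, BICC1 and ATP7A, the last a copper transporter, had 0 reads in both control libraries. Against the floor of 0.231 CPM they were at least 54.2-fold, 38.2-fold, 28.7-fold, 23.7-fold, 22.1-fold, 18.2-fold, 16.4-fold and 16.2-fold higher, in that order. The bound of TRAPPC3L was 4.11-fold without the sevoflurane male library, where its call was lost (edgeR adjusted p = 0.120), and 40.1-fold without the sevoflurane female, and that of IGF2BP3 was 15.6-fold without the sevoflurane male. ZDBF2, an imprinted gene, rose from 0.332 ± 0.285 to 106.4 ± 39.4 CPM (log2 fold change 8.39 ± 0.65 SE). RICTOR, a subunit of the kinase complex mTORC2, had 3 reads in the controls and 1169 in the sevoflurane libraries, a ratio of 341 (95% counting interval 116 to 1660). All 3 control reads of RICTOR lay in the control female library, and the ratio was 197 (67.2 to 956) without the control male and at least 145-fold without the control female, against a floor of 0.267 CPM. ZDBF2 was at 7.64 without the control female library, and without the control male, where 2 control reads were left, at a ratio of 807 (223 to 6660).

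The genes of largest fall included transporters of epithelia and several secreted proteins. KCNJ13, an inward-rectifier potassium channel, and C7H14orf180 had 0 reads in the sevoflurane libraries, and were at least 84.1-fold and 33.6-fold lower against a floor of 0.198 CPM. These bounds were 4.94-fold and 6.26-fold without the control male library, and 163-fold and 61.0-fold without the control female. SLC22A8, an organic anion transporter, fell by 7.83 ± 0.93 (log2), from 54.8 ± 47.7 to 0.232 ± 0.0600 CPM. Log2 fold changes were −8.47 ± 2.30 for ECRG4, −7.31 ± 1.24 for SLC13A4, −6.89 ± 2.07 for WFIKKN2, −6.66 ± 1.42 for SERPIND1, −6.39 ± 1.36 for HBQ1 and −6.33 ± 1.53 for SOD3. SLC16A11 had 2 reads in the sevoflurane libraries, and was higher in controls by a ratio of 89.6 (24.4 to 747), which was 16.8 (4 to 150) without the control male and 189 (51.3 to 1570) without the control female. The control male library set much of this group. ECRG4 stood at 7.11 CPM in the control female, 1478 in the control male, 2.79 in the sevoflurane female and 1.37 in the sevoflurane male library. Without the control male library, the calls of ECRG4 (−1.80) and SLC16A11 were lost, and the log2 fold changes were −2.87 for WFIKKN2, −3.79 for HBQ1 and −2.98 for SOD3. In that fit SLC13A4 was at −5.52 and SLC22A8 at −6.49. Without the sevoflurane female library SOD3 was at −7.84 and ECRG4 at −9.06. In the same fit 1 or 2 sevoflurane reads were left for 3 genes, which were higher in controls by a ratio of 807 (223 to 6670) for SLC13A4, 3380 (935 to 27900) for WFIKKN2 and 286 (51.2 to 11300) for SERPIND1. Without the sevoflurane male library WFIKKN2 was at −5.92, SLC13A4 at −6.47, SOD3 at −5.62 and SERPIND1 at −6.06. Leaving out the control female library moved ECRG4 to −9.44, SLC22A8 to −8.50, SLC13A4 to −8.07, WFIKKN2 to −7.84, HBQ1 to −7.25 and SOD3 to −7.25, and SERPIND1 was at −7.58 without the control male. SERPIND1 was at 32.2 CPM in the control female and 2.67 in the control male library, and its log2 fold change without the control female was −3.94. KCNJ13, C7H14orf180, ECRG4, SERPIND1, SLC16A11, HBQ1 and SOD3 lost their calls without either sevoflurane library, and WFIKKN2 without the sevoflurane male.

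Subunits of GABA-A and glycine receptors, the inhibitory ion channels on which sevoflurane acts, rose in most cases. Of 17 tested, 12 rose, 1 fell and 4 were not called (15 called when adjusted over the list alone), and the median log2 fold change was 2.24 (2.90 without the control female) beside 2.94 for long A- and U-rich messenger RNAs. GABRB2 (ENSMMUG00000018044) rose from 0.922 ± 0.173 to 107.1 ± 5.51 CPM, a log2 fold change of 6.83 ± 0.35 (edgeR adjusted p = 0.00141, higher in both sexes). GABRG1 rose by 5.21 ± 0.55 (6.12 without the control female library) and GABRA3 by 3.35 ± 0.48. The subunit that fell, outside the naming rule and chosen after its values were seen, was GABRD (−1.62 ± 0.50), and its call was lost with library totals, without the control female and without the sevoflurane male library; without the sevoflurane female library it was −2.51. The list was called upward by limma's camera (adjusted p = 0.00181), but not with an estimated correlation (adjusted p = 0.951) or by fry (adjusted p = 0.129). Without the sevoflurane male library 6 members rose.

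Excitatory receptor and synaptic genes rose in part. Of 17 ionotropic glutamate receptor subunits, 7 rose and 0 fell (7 adjusted over the list alone), with a median of 0.74, which was 1.37 without the control female. GRIN3A and GRIN2B, subunits of the NMDA receptor, rose by 5.52 ± 0.48 and 3.67 ± 0.54, and GRIN2B was at 4.44 without the control male library. Of 29 synaptic vesicle and scaffold genes, 13 rose and 2 fell (17 adjusted over the list alone), with a median of 0.66. DLG2, a postsynaptic scaffold, rose from 6.47 ± 1.74 to 289.3 ± 61.0 CPM (5.47 ± 0.37). RIMS1 and BSN, proteins of the presynaptic active zone with long messenger RNAs, rose by 4.87 ± 0.37 and 4.44 ± 0.42. The 2 that fell, named after their values were seen, were HOMER3 (−2.55 ± 0.48, and −3.25 without the sevoflurane female library) and SYN1 (−1.31 ± 0.31), and the call of SYN1 was lost without the sevoflurane male library. In all, 4 synaptic genes fell without the control male library, and 3 without the sevoflurane female. Neither list was called (limma's camera, adjusted p = 0.136 and 0.0578). Of 13 background potassium and HCN channels, 2 rose and 1 fell (1 adjusted over the list alone), with a median of 0.02. That median was −0.06 without the sevoflurane female, where 1 rose and 2 fell, and −0.66 without the sevoflurane male, where 1 rose and 0 fell.

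Of 29 immediate early genes, 2 rose, 9 fell and 18 were not called (11 adjusted over the list alone), with a median of −1.05 beside −1.46 for short messenger RNAs. That median was −1.71 without the control male library, where that of short messenger RNAs was −1.43, and −0.45 without the control female, where it was −1.45. NPAS4 (ENSMMUG00000015982), induced by neuronal calcium entry, fell from 86.4 ± 63.0 to 2.09 ± 0.447 CPM, a log2 fold change of −5.37 ± 0.65 (edgeR adjusted p = 0.00276, lower in both sexes). NPAS4 was at −4.30 without the control female and −6.00 without the control male library. EGR4 changed by −3.26 ± 0.44 (−2.64 without the control female) and JUND by −2.44 ± 0.34. NR4A1 (−3.85 ± 0.67) and FOS (−2.15 ± 0.52) also fell, both outside the naming rule and chosen after their values were seen. Without the control female library FOS was at −1.22 and NR4A1 at −2.62, and without the control male at −2.74 and −4.54. The call of FOS was lost without the sevoflurane male library. The 2 that rose were HOMER1, whose gene also encodes long scaffold isoforms (4.78 ± 0.48, and 5.53 without the control female), and EGR3 (2.83 ± 0.84, named after its values were seen). The call of EGR3 was lost without either sevoflurane library, and it was 4.70 without the control female, 2.03 without the control male and 2.22 without the sevoflurane female. The list was called downward by limma's camera (adjusted p = 0.0414), but not with an estimated correlation (adjusted p = 0.951) or by fry (adjusted p = 0.484). Its camera call was lost without the control female (adjusted p = 0.337), the sevoflurane female (0.0652) or the sevoflurane male library (0.0780). Without the control male library 16 members fell, and without the sevoflurane male 6 fell. Without the control female library 4 rose, and 1 without either sevoflurane library.

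Most nuclear genes of the respiratory chain, many of them with short messenger RNAs, were called lower. Of 35, 1 rose, 25 fell and 9 were not called (30 adjusted over the list alone), and the median of −1.46 matched that of the short messenger RNAs to 2 decimals. COX6B1, a subunit of cytochrome c oxidase, fell from 278.3 ± 60.7 to 50.9 ± 3.54 CPM (−2.45 ± 0.28, edgeR adjusted p = 0.00251, lower in both sexes). ATP5MC1, of the ATP synthase ring, fell from 181.6 ± 39.0 to 26.2 ± 3.29 CPM (−2.79 ± 0.29). The gene that rose, named after its values were seen, was NDUFS1 (1.49 ± 0.26), the largest subunit of complex I. The list was called downward by limma's camera (adjusted p = 2.36e-06), but not with an estimated correlation (adjusted p = 0.951) or by fry (adjusted p = 0.0906).

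Among glial markers, those of microglia were called lower more often than higher. Of 16, 1 rose, 10 fell and 5 were not called (12 adjusted over the list alone), with a median of −1.46, the same as the short messenger RNAs to 2 decimals. C1QA, a chain of complement C1q, fell from 80.1 ± 7.13 to 18.1 ± 0.297 CPM (−2.15 ± 0.27, edgeR adjusted p = 0.00297, lower in both sexes). TYROBP, a signalling adaptor, changed by −3.10 ± 0.45. PTPRC, the CD45 gene, rose by 2.69 ± 0.62 (named after its values were seen), a call lost without either sevoflurane library. The list was called downward by limma's camera (adjusted p = 0.00817) and by fry (adjusted p = 0.0353), but not with an estimated correlation (adjusted p = 0.951). Of 15 astrocyte markers, 3 rose and 4 fell (8 adjusted over the list alone), with a median of 0.16. The balance of calls turned with library totals, where 5 rose and 2 fell with a median of 0.38. With TMM the median depended on single libraries. That median was −0.25 without the control male and 0.62 without the control female library, and 2 fell without either sevoflurane library. SLC1A2, the main glutamate transporter of astrocytes, rose from 22.3 ± 9.01 to 438.9 ± 97.7 CPM (4.30 ± 0.41), and the bicarbonate transporter SLC4A4 rose by 5.38 ± 0.39. GFAP, the astrocyte intermediate filament, fell from 2327 ± 13.5 to 402.8 ± 210.7 CPM (−2.53 ± 0.43), and S100B changed by −1.94 ± 0.32. GFAP was at −3.19 without the sevoflurane male library. Of 23 myelin and oligodendrocyte markers, 2 rose and 4 fell (6 adjusted over the list alone), with a median of −0.54 that became 0.71 without the control male library, where 5 rose and 1 fell. Without the control female library 10 of them fell, with a median of −1.17, and without either sevoflurane library 0 fell. Without the sevoflurane male library 1 of them rose. Of 11 precursor markers, 4 rose and 2 fell (8 adjusted over the list alone), with a median of 0.86, and 2 rose without the sevoflurane male and 3 fell without the control female. PTPRZ1 rose by 1.54 ± 0.29, and OLIG2, a transcription factor of that lineage, changed by −1.74 ± 0.33.

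Vascular and connective tissue markers were mixed. Of 9 fibroblast and meningeal markers, 0 rose and 4 fell (4 adjusted over the list alone), with a median of −1.24 (−0.59 without the control female) beside −1.46 for short messenger RNAs. COL1A1, a collagen chain, fell from 135.5 ± 46.4 to 10.1 ± 3.42 CPM (−3.74 ± 0.41). The list was called downward by limma's camera (adjusted p = 0.0414), but not with an estimated correlation (adjusted p = 0.951) or by fry (adjusted p = 0.316). Its camera call was lost without the control female (adjusted p = 0.184), the sevoflurane female (0.0652) or the sevoflurane male library (0.0857), and 7 members fell without the control male. Of 12 endothelial markers, 2 rose and 2 fell (4 adjusted over the list alone), with a median of −0.0069 that turned to 0.23 with library totals and to 0.07 without the control male library. Without either sevoflurane library 1 endothelial marker rose, and without the sevoflurane male 1 fell. CLDN5, a tight junction protein, changed by −2.63 ± 0.29, and FLT1, a receptor for vascular growth factor, rose by 4.97 ± 0.75. FLT1 was at 6.95 without the control female and 4.20 without the control male library. Of 10 pericyte and smooth muscle markers, 2 rose and 2 fell (4 adjusted over the list alone), with a median of −0.92, and 4 fell without the control male or the sevoflurane female. RGS5 rose by 1.93 ± 0.34 and ACTA2 changed by −3.23 ± 0.43 (−2.59 without the control female). Of 4 red blood cell markers, 1 fell (1 adjusted over the list alone), and 0 fell without the sevoflurane male.

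Neuronal markers went both ways. Of 14 excitatory cortical-type markers, 2 rose and 2 fell (3 adjusted over the list alone), with a median of 0.56. NRGN, a postsynaptic calmodulin-binding protein with a short message, fell from 4110 ± 715.5 to 734.9 ± 353.6 CPM (−2.48 ± 0.43), and the transcription factor ETV1 rose by 2.86 ± 0.42. NRGN was at −3.07 without the sevoflurane female library. Of 16 inhibitory interneuron markers, 2 rose and 2 fell (3 adjusted over the list alone), with a median of −0.54. The medians of both lists turned without 1 library, the excitatory one to −0.25 without the sevoflurane female and the inhibitory one to 0.45 without the control female. Without the control female 5 excitatory markers rose and 3 fell, and 3 inhibitory markers rose and 4 fell. Without the control male 3 excitatory markers rose and 1 fell, and 1 inhibitory marker rose. Without the sevoflurane female 1 excitatory marker rose and 1 fell, and 1 inhibitory marker rose and 3 fell, and without the sevoflurane male 3 excitatory and 1 inhibitory markers rose. Of 15 striatal-type spiny neuron markers, 2 rose and 6 fell (10 adjusted over the list alone), with a median of −0.91. The dopamine receptor DRD1 rose by 3.03 ± 0.56, and was at 3.70 without the control male and 2.39 without the sevoflurane male. Of the striatal-type markers 0 fell without the sevoflurane male library (median −0.31), 2 without the control male (−0.18) and 3 without the sevoflurane female (−1.84). Without the control female or control male 3 rose, and without the sevoflurane female 1. The neuropeptide list also holds receptors. Of its 21 tested genes, 1 rose and 8 fell (9 adjusted over the list alone), with a median of −1.13. CCK, SST and NPY changed by −2.02 ± 0.30, −1.98 ± 0.39 and −1.80 ± 0.34, and SST was at −2.57 without the sevoflurane female. The member that rose, named after its values were seen, was the receptor NPY1R (3.44 ± 0.80), which was at 5.41 without the control female and 2.64 without the control male, and lost its call without either sevoflurane library. Without the sevoflurane male library 0 neuropeptide genes rose and 4 fell, and without either control library 2 rose. Of 12 immature neuron markers, 4 rose and 1 fell (5 adjusted over the list alone), with a median of 0.76. DPYSL3, a regulator of growth cones, rose by 3.27 ± 0.26 and DCX, a microtubule protein of migrating neurons, by 5.54 ± 0.74. For DCX 1 control read was left without the control female library, and the ratio was 99.8 (17.8 to 3950). The member that fell, named after its values were seen, was the tubulin gene TUBB3 (−1.46 ± 0.29). None of these 5 lists was called by limma's camera with adjustment.

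Clock, stress and metabolic lists were not called by limma's camera with adjustment, and single members moved. Among the 15417 tested genes, 40.7% were called for sevoflurane. A few called members therefore do not set a list apart, here or in the other lists. Of 18 circadian clock genes, 8 rose and 1 fell (9 adjusted over the list alone), with a median of 0.98 and a list adjusted p of 0.0714 (limma's camera). The repressor NR1D2 rose by 5.34 ± 0.41 and CLOCK by 4.48 ± 0.40, while DBP, named after its values were seen, changed by −1.99 ± 0.54 and was at −3.09 without the sevoflurane female and −1.37 without the sevoflurane male library. Without the sevoflurane female library 4 clock genes rose and 2 fell, and without the control male 2 fell. Of 17 heat shock genes, 4 rose and 0 fell (3 adjusted over the list alone), with a median of 0.34. Without the control male 1 rose, without the control female 2 rose and 2 fell, and without the sevoflurane female 3 rose and 2 fell, with a median of −0.21. HSPH1 rose by 1.42 ± 0.31, and HSP90AA1 rose from 1807 ± 238.4 to 3569 ± 457.4 CPM (0.98 ± 0.29). The call of HSP90AA1 was lost without any 1 of the 4 libraries, and that of HSPH1 without the control male. Of 19 unfolded protein response genes, 0 rose and 5 fell (5 adjusted over the list alone), with a median of −0.13 that turned to 0.10 with library totals, and 0 fell without the sevoflurane male library, with a median of 0.05. With library totals 2 of these genes fell. Without the sevoflurane female the median was −0.73. With the control male left out 3 fell. CALR, a chaperone of the endoplasmic reticulum, changed by −1.07 ± 0.29, a call lost with library totals and without either male library. Of 20 hypoxia and glycolysis genes, which had 21 IDs, 3 rose and 4 fell (6 adjusted over the list alone), with a median of 0.05 where camera's direction was down. With library totals 3 rose and 2 fell. Without the control male 1 rose and 1 fell, without the sevoflurane female 4 rose and 2 fell, and without the sevoflurane male 2 rose and 2 fell, with a median of −0.18. KDM3A rose by 2.00 ± 0.32 and ALDOA, a glycolytic enzyme, changed by −1.44 ± 0.28. Of 19 glucocorticoid-responsive genes, 4 rose and 2 fell (6 adjusted over the list alone), with a median of 0.11. The median was −0.01 without the control male, where 4 fell, and −0.05 without the sevoflurane female. Without the control female 3 fell, and without the sevoflurane male 1. KLF9 rose by 3.75 ± 0.55 (4.68 without the control female) and MT2A, a metallothionein with a short message, changed by −2.64 ± 0.38. Of 19 cholesterol synthesis genes, 7 rose and 2 fell (9 adjusted over the list alone). IDI1, an isomerase of the pathway, rose by 3.06 ± 0.30, and PMVK changed by −2.10 ± 0.29. MVD, named after its values were seen, changed by −1.08 ± 0.32, a call lost with library totals and without either male library. Of the cholesterol genes 4 rose and 1 fell without the control male library, and without the sevoflurane male 1 fell.

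**Figure D3:**
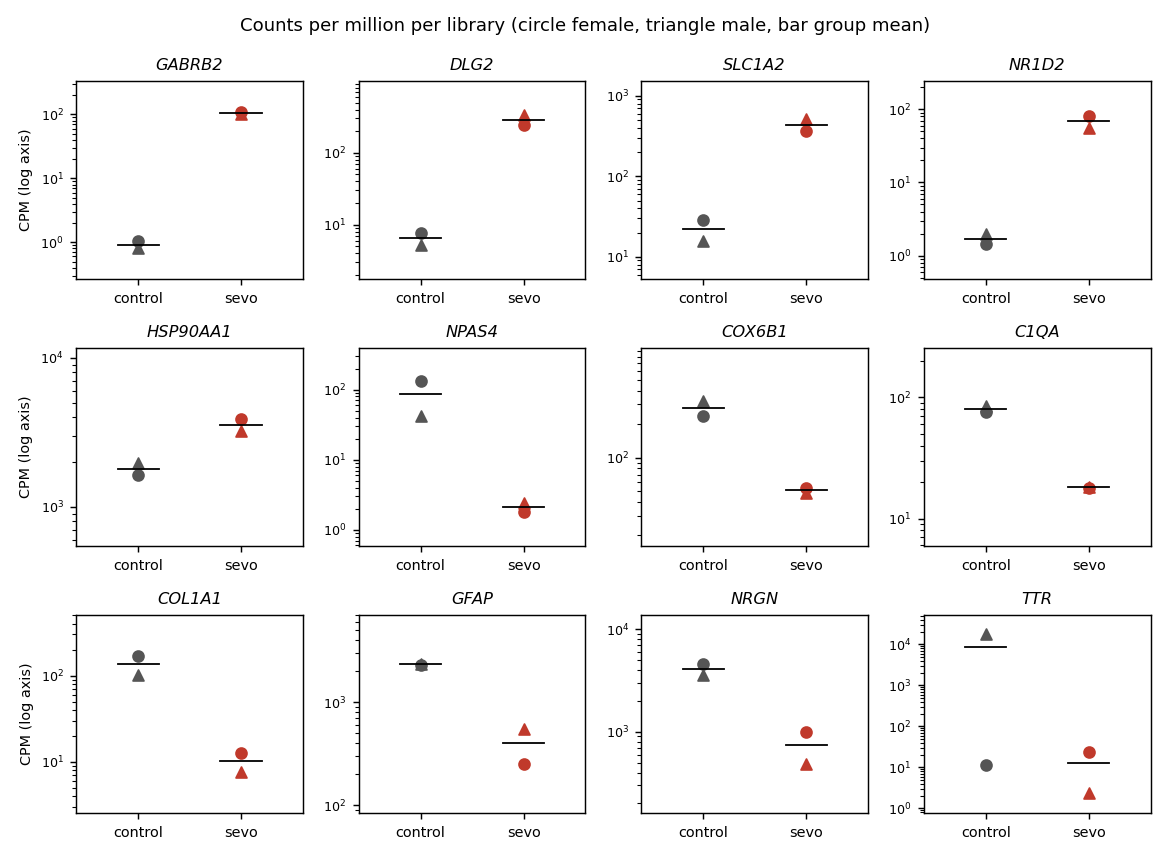
CPM (log axis) of 12 genes in each library, circles for females, triangles for males, black bars for group means of 2 libraries. GABRB2, DLG2, SLC1A2, NR1D2 and HSP90AA1 lie higher in both sevoflurane libraries, NPAS4, COX6B1, C1QA, COL1A1, GFAP and NRGN lie lower, and TTR stands at 17580 CPM in the control male library alone.

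Of 18 m6A regulators, 7 rose and 1 fell (8 adjusted over the list alone), with a median of 0.57 that was the same with IGF2BP3 at its bound. ZC3H13, of the methyltransferase complex, rose by 2.60 ± 0.26 and the reader YTHDF1 by 1.88 ± 0.35. The member that fell, named after its values were seen, was RBM15B (−0.97 ± 0.30), a call lost with library totals, with upper quartile scaling and without any 1 of the libraries. The list was called by fry (adjusted p = 0.0181) and not by limma's camera (adjusted p = 0.313), and 3 members rose without the control male library, 4 without either female library and 5 without the sevoflurane male. Of 22 apoptosis genes, 3 rose and 2 fell (4 adjusted over the list alone). Leaving out the control male, 2 rose and 5 fell, without the sevoflurane female 2 rose and 3 fell, without the control female 2 rose, and without the sevoflurane male 1 rose. APAF1, the apoptosome scaffold, rose by 3.50 ± 0.47, while BAD and BAX, promoters of cell death with short messages, changed by −2.83 ± 0.33 and −2.07 ± 0.32. Of 9 inflammatory genes, 1 rose and 1 fell (2 adjusted over the list alone), 0 moved without the sevoflurane female, and 0 fell without the sevoflurane male. Of 16 proliferation markers, 3 rose and 0 fell (1 adjusted over the list alone), and without the control female or either sevoflurane library 0 rose, and without the control male 1. Of 10 hippocampal markers, 2 rose and 1 fell (3 adjusted over the list alone), 4 rose without either control library, 3 without the sevoflurane female, and 1 rose and 0 fell without the sevoflurane male. Of 11 thalamic and hypothalamic markers, 0 rose and 2 fell (0 adjusted over the list alone), and 0 fell without the control male or either sevoflurane library, and 3 without the control female. Of 6 choroid plexus markers, 1 fell (1 adjusted over the list alone), and 6 of 8 tested fell without the control female, 1 of 5 rose without the control male, and 0 fell without either sevoflurane library. Of 9 ependymal markers, 0 rose and 0 fell (0 adjusted over the list alone) by edgeR, and their median of −1.065 was −1.95 without the control female. With sex as a covariate RSPH1 and DNAI1 were called lower (edgeR adjusted p = 0.0101 and 0.0285).

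Sex differences were fewer. With condition held, 283 genes were called between males and females by edgeR, 123 higher in males and 160 lower, and 36 of the 283 were also called for sevoflurane. TESPA1, a gene of calcium signalling, was lower in males by a log2 fold change of −5.51 ± 0.39 (edgeR adjusted p = 2.90e-07). TMEM155 (−4.18 ± 0.38) was also lower in males. The serotonin receptor HTR2C (4.25 ± 0.39) and IRAG2 (4.05 ± 0.42) were higher in males, with HTR2C at 139.5 against 4.50 CPM in controls and 102.2 against 8.54 CPM after sevoflurane. With 1 animal per sex and condition, sex cannot be separated from the individual. With sex as the only term 0 genes were called by edgeR (168 at an unadjusted p under 0.05). That model leaves the difference between conditions in the residual, so its lack of calls does not bear on the 283. It is the only model 3 libraries allow, and with it TESPA1 ranged from −7.74 to −3.45 when 1 library was left out.

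As lists, 12 of 32 were called between the sexes by limma's camera, 4 higher in males and 8 lower. None of them was called with an estimated correlation (adjusted p = 0.779 for each), and these tests were chosen after seeing the data. By fry 1 list, the pericyte and smooth muscle markers, was called (adjusted p = 0.0496). Of 23 myelin markers, 5 were higher and 0 lower in males (12 adjusted over the list alone), with a median of 1.07, which was 1.75 in controls and 0.40 after sevoflurane. Of 29 immediate early genes, 0 were higher and 4 lower in males (10 adjusted over the list alone), with a median of −0.82, which was −1.39 in controls and −0.34 after sevoflurane. Limma's camera gave an adjusted p of 1.71e-10 for myelin and 6.38e-06 for immediate early genes. Choroid plexus, ependymal and striatal-type markers were also called higher in males (limma's camera, adjusted p = 0.00729, 0.00298 and 0.0131). Their medians were 5.12, 1.85 and 1.34 in controls and −0.78, −0.26 and −0.27 after sevoflurane, and 1 gene of each list was itself called higher in males. Fibroblast, synaptic, inhibitory neuron, clock, pericyte, unfolded protein response and glucocorticoid-responsive lists were called lower (limma's camera, adjusted p = 0.000702, 0.00298, 0.00298, 0.00605, 0.0120, 0.0451 and 0.0484).

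The third split of the 4 libraries set the control female and sevoflurane male against the control male and sevoflurane female. It gave 0 called genes by edgeR, with 16 at an unadjusted p under 0.05, and 3 by DESeq2 and 0 by limma-voom. Its model leaves the difference between conditions in the residual. The lack of calls therefore does not bear on the genes called for sevoflurane or between the sexes. An interaction of sex and sevoflurane could not be tested, because 4 libraries leave no residual degree of freedom.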

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

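The tests of the choroid plexus markers and of the immediate early genes against short messenger RNAs and the bootstrap interval of the excitatory markers were chosen only after the result was seen, as were the lists of long and short messenger RNAs, though not the values of their members.

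The first pattern is the breadth of the sevoflurane difference, 6278 called genes. A shift against long transcripts whatever their base composition was predicted to lift both long lists over the short one. The list rich in G and C lay 1.99 log2 above it (95% bootstrap interval 1.33 to 2.71 over 10000 resamples of genes, and 0.82 to 2.31 around 1.62 without the sevoflurane female library). A shift tied to A and U was predicted to part the long lists, which lay 2.41 apart (1.18 to 3.61), so both may contribute, as a difference in RNA or library handling could. Whether the shift between long and short transcripts is the whole of the fall of immediate early genes stays open, since their median lay 0.414 above that of short messenger RNAs with an interval of −0.53 to 0.94. The value was 1.0 (0.22 to 1.67) without the control female, −0.29 (−1.17 to 0.53) without the control male, 0.12 (−0.94 to 0.87) without the sevoflurane female and 0.22 (−0.65 to 1.01) without the sevoflurane male library. The bootstrap intervals here and below resample genes as if they were independent, and do not carry the spread between libraries. Also open is a different share of neurons in the tissue, which was not tested as a cause. Among both the excitatory and the inhibitory markers 2 rose and 2 fell. Of the synaptic genes 13 rose and 2 fell, and of the microglial markers 1 rose and 10 fell. The effect of sevoflurane itself stays open too, since the design confounds it with any difference in handling.

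The second pattern is TTR, at 11.6 CPM in the control female, 17580 in the control male, 23.3 in the sevoflurane female and 2.33 in the sevoflurane male library. For the choroid plexus genes in the control male library, choroid plexus tissue in that dissection is a candidate explanation. Of 5 tested markers other than TTR, 3 (KCNJ13, CLIC6 and PRLR) were at least 4-fold higher there than in every other library, while KL and SLC4A5 were not. KL and SLC4A5 stood at 1.33 and 2.31 CPM in the control male and at 0 and 0.261 CPM in the control female. In the sevoflurane female they stood at 2.72 and 3.29 CPM, a comparison that crosses the difference between conditions. At 60% of the markers, the test lies between its bounds and leaves this explanation open. Sex and sevoflurane stay untested, since this is 1 animal.

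The third pattern is the 283 genes called between the sexes. A different share of cortical-type tissue in the dissections was predicted to move excitatory cortical-type markers alike in both conditions. Their median male over female difference was −0.51 in controls (95% bootstrap interval −1.19 to 0.38) and −0.171 after sevoflurane (−1.02 to 1.0). The bound set beforehand against this explanation was a median within 0.5 of 0 in either condition. It was met after sevoflurane, so by that rule the prediction failed. The bootstrap interval, chosen after the result was seen, runs beyond 0.5 on both sides there, so the explanation is not excluded. Of the 14 markers 2 were called higher and 3 lower in males (8 adjusted over the list alone), moves both ways that a median does not show. Sex itself and differences between individuals stay open and untested.

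Several sevoflurane fold changes had opposite signs in the 2 sexes, with 1 library for each sex and condition, and none of these differences was tested. For TTR the log2 fold change was 0.996 in females and −12.79 in males, a male minus female difference of −13.8. Medians of choroid plexus markers were 2.16 and −4.55 (difference −6.71), of ependymal markers 0.26 and −1.86 (−2.12), and of myelin markers 0.44 and −0.997 (−1.44). Unfolded protein response genes had 0.05 and −0.73 (−0.782), heat shock genes 0.54 and −0.12 (−0.661), and proliferation markers 0.41 and −0.22 (−0.634). Hypoxia genes had −0.25 and 0.27 (0.520), and astrocyte markers −0.0092 and 0.49 (0.502). Endothelial markers had 0.03 and −0.18 (−0.215), and glucocorticoid-responsive genes 0.06 and −0.04 (−0.102).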

How the results depend on the processing

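The test against a 2-fold change was chosen after seeing the data; the other alternatives were fixed before. The 6278 genes called for sevoflurane became 3030 against a 2-fold change, by construction, and 3469 to 5800 when 1 library was left out, with fewer libraries. Under the other alternatives the count was 6114 to 7825. Sex as a covariate, which is also the replicate block, gave 7825 genes, all 6278 among them, and 7 lists, with the 5 lists among them. The labels do not pair the libraries. The genes it added include TESPA1, with an edgeR adjusted p for sevoflurane of 7.56e-06 against 0.264 without the block, and the ependymal markers RSPH1 and DNAI1. The 283 genes called for sex became 603 without a filter, 610 with limma-voom, 0 with sex alone in the model and 0 to 31 with sex alone and 1 library left out, which changes 2 choices at once; the cause was not tested. The third split gave 0 genes, 3 with DESeq2, and 0 to 16 when 1 library was left out; the cause was not tested. The 5 lists called became 0 with an estimated correlation, 2 with fry and 3 to 10 when 1 library was left out, and 4 with the stricter filter, where the list of fibroblast and meningeal markers lost its call (adjusted p = 0.0586). The correlation of the fold changes in the 2 sexes, 0.859, was 0.913 with the stricter filter, which tests fewer genes, and 0.841 to 0.870 otherwise. TTR, at −9.42 (edgeR adjusted p = 0.0501), ranged from −11.86 to 0.10 (0.0990) when 1 library was left out and reversed only without control replicate 2. It passed the threshold with DESeq2, with no filter, with the stricter filter, with thinning and without control replicate 1. With limma-voom KCNJ13, ECRG4, WFIKKN2, SERPIND1, SLC16A11, HBQ1 and SOD3 lost their calls, and with library totals CALR (−0.83), GABRD, MVD and RBM15B did. Where an arm kept 1 library, that library was assumed to vary like the other group. Thinning to the smallest library left 6273 genes called. With 2 libraries per group the simulated test recovered 4% of 2-fold changes, in counts where 200 genes changed. That share need not hold for these data, but an uncalled gene is not shown to be unchanged.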

Other observations

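Within males, Y-linked genes also went both ways after sevoflurane, a comparison of 2 libraries with no test that was chosen after seeing the data. Of the 11 matched genes, 7 were higher and 4 lower in the sevoflurane male than in the control male library. DDX3Y, an RNA helicase, stood at 51.1 CPM in the control male and 138.7 in the sevoflurane male library, and the ubiquitin protease USP9Y at 28.6 and 115.6 CPM. UTY, ZFY, NLGN4Y, TBL1Y and TMSB4Y were also higher after sevoflurane, the last with 3.64 and 6.04 CPM. The ribosomal protein genes RPS4Y1 and RPS4Y2, with near-identical relatives, stood at 324.7 and 122.5 CPM, and at 124.0 and 51.0 CPM. EIF1AY stood at 73.3 and 56.3 CPM, and the histone demethylase KDM5D at 15.7 and 12.8 CPM.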
